A study of Mus musculus with 22 samples.

How the data were processed

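Gene expression was measured in 22 lymphoma samples from mice of a mixed 129/C57Bl6 background. In these mice the tumour suppressor p53 (Trp53) carries floxed alleles that Cre recombinase deletes, and Cre is driven by Mb1 (Cd79a), a promoter active in the B lineage. Some mice also carry a cyclin D2 (Ccnd2) transgene in the Rosa26 locus. Per the labels' protocols, RNA was extracted from fresh lymphoma cells with a phenol-based reagent and a column kit, and libraries were made with a kit that sequences from the 3' end of messenger RNA, so each transcript contributes tags near its end and transcript length is not corrected for. The reads were checked with FastQC and aligned with STAR to GRCm38, per the submitters' processing notes. Tool versions, the read counter, its strand setting and the gene annotation are not given in the sources used here. The deposited values are raw counts per Ensembl gene and sample, with no normalization, and they were used as deposited. Reads of overlapping genes, antisense genes and near-identical copies such as haemoglobin genes, major histocompatibility genes and immunoglobulin segments can be split or shared in such counts, so their values are less certain.

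Gene symbols and coordinates were taken from GENCODE release M21, an annotation of GRCm38, and 52403 of 52636 gene identifiers matched when version suffixes were ignored. Library totals ran from 2693399 to 8146613 counts. Samples were grouped by genotype, by the submitters' immunophenotype label (MCL-like or non-MCL, where MCL is mantle cell lymphoma), and by primary tumour or transplant. For 6 transplant samples the sample title says non-MCL while the immunophenotype field says MCL-like; they were grouped by the immunophenotype field. The tumour type field names the organ or tumour site. The count column of Ccnd2 non-MCL primary replicate 3 is named oTP14, as in that sample's description, while its title says oTP14b. The mouse was the unit of replication: the libraries of p53-only replicates 2 and 5, which share a mouse, were summed, as were transplant libraries from the same primary mouse. No pair of libraries was alike within counting noise; the smallest chi-square per degree of freedom among the 231 pairs was 5.42.

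Each comparison was fitted with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the tool's default low-count filter on the groups, robust dispersion shrinkage and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The 13 primary mice shared a fit for MCL-like against Ccnd2 non-MCL (4 vs 3) and for Ccnd2 non-MCL against p53-only (3 vs 6), and a fit of 2 groups was used for MCL-like against all non-MCL (4 vs 9). MCL-like transplants were compared with primaries of the same 3 mice, with mouse as a block, because the labels name the primary mouse of each transplant. Deviations from the group means, over 8598 genes, correlated at 0.32, 0.312 and 0.405 within a mouse, and at most at 0.00252 between mice. Deviations from a mean of 3 mice cancel out, so positive values within a mouse force those between mice down. The low values between mice are therefore no separate evidence for the pairing. Standard errors (SE) of log2 fold changes are the absolute log2 fold change divided by the square root of F. Levels in comparisons are TMM-scaled CPM (counts relative to a common library total) per mouse, as mean ± SD. Levels by library or group are unscaled CPM, and both were computed here from the deposited counts. Exact binomial intervals cover counting error only.

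The gene lists covered B1, follicular, marginal zone, pro-B and pre-B, germinal centre, plasma and general B cells, B cell receptor signalling and its early response, NF-kB targets, the G1 cell cycle, proliferation, p53 and Myc targets, MHC class II, interferon response, and markers of T cells, NK cells, macrophages, neutrophils, erythroid cells, stroma and endothelium, and thymic epithelium, together with a list of key genes. These 24 lists were fixed before the data were examined. They were tested with camera (limma 3.58.1, preset correlation 0.01), which sets a list against all other genes, with adjustment over the 24 lists. Camera with an estimated correlation, and fry, which tests whether the genes of a list move on balance one way, were alternatives. Genes named in the text follow a rule fixed before the data were examined: the key genes; per comparison the 8 largest increases and 8 largest decreases among called genes with at least 10 CPM in the higher group, no overlap between the groups and an ordinary symbol; and up to 3 members per list with the lowest adjusted p. Vpreb1 and Cd79b, and in the comparison with all non-MCL mice Lyn, Nfkb1 and Nfkbie, were named after their values were seen. Igll1 was also named outside the rule. Results of a few genes, in the text and in the search for outlying libraries, are not reported here. Heavy chain V segments were compared between mice by Fisher's exact test, and shares of IgM by a two-sided exact permutation test.

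Alternatives were other scalings, filters and fold thresholds, DESeq2 1.42.0, fits restricted to the groups compared, all mice with transplants, limma-voom over all libraries with mouse as a random effect, spleen tumours alone, each mouse left out, and the tumour name prefix. Tumour names begin with TP (17 libraries) or oTP (5 libraries), a difference whose meaning the labels do not give; libraries of the prefixes were compared, left out or modelled as a covariate. Leaving out haemoglobin, mitochondrial and Gm42418 counts, counting MCL-like transplant replicate 5 under another mouse, using all libraries for V segments, and testing the genes called against all non-MCL mice in other mice were chosen after seeing the data. The pipeline was tested on simulated counts with 200 genes changed 4-fold. With edgeR it recovered 7% of them at an adjusted p under 0.05 for MCL-like against Ccnd2 non-MCL, with 0 false calls among 12636 genes, 47% for MCL-like against all non-MCL, with 5 false calls among 12660 genes, 28% for Ccnd2 non-MCL against p53-only, with 4 false calls among 12577 genes, and 42% for transplant against primary, with 18 false calls among 11636 genes. DESeq2 recovered 44.5% for MCL-like against Ccnd2 non-MCL, with 18 false calls among 12967 genes, and limma-voom over the 22 libraries recovered 63.5%, with 7 false calls among 12465 genes. The simulation drew libraries of the same mouse independently, while their estimated correlation in the data was 0.445 for this comparison. The limma-voom figures therefore do not show how it performs on these data. DESeq2 was simulated for this comparison alone and called 89 changed and 18 unchanged genes. The edgeR run for transplant against primary called 84 and 18. In both runs the false share of calls was above 0.05.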

Results

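Gene expression was profiled by 3' end sequencing in 22 lymphoma libraries from 15 mice with a B lineage deletion of p53, with or without a Ccnd2 transgene. The submitters sorted the tumours into an MCL-like immunophenotype, resembling mantle cell lymphoma, and a non-MCL immunophenotype. The 14 primary libraries came from 4 MCL-like mice with the transgene, 3 non-MCL mice with the transgene (Ccnd2 non-MCL), and 6 non-MCL mice without it (p53-only), of which 1 mouse gave a pair of libraries. The 8 transplant libraries came from tumours grown in immunodeficient NSG mice, 6 of them MCL-like and 2 labelled Ccnd2 non-MCL. Total counts were 3159419 to 4739716 in MCL-like primary libraries, 2693399 to 8146613 in Ccnd2 non-MCL primary libraries, and 2936387 to 6057077 in p53-only libraries. They were 3050785 to 5825652 in MCL-like transplants. The Ccnd2 non-MCL transplants held 3780128 and 3934589 counts. Most tumours came from the spleen. MCL-like replicate 1 was a mesenteric lymphoma. Mediastinal tumours, a thymoma and lymphomas of unstated site were among the non-MCL samples.

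Ccnd2, which encodes a G1 cyclin (ENSMUSG00000000184, GRCm38 chromosome 6, 127125162 to 127152193), was high in every MCL-like tumour and varied widely in the others. It measured 1760 ± 410 CPM (SD, n = 4) in MCL-like primaries and 1990 ± 89.9 CPM (n = 4 mice) in MCL-like transplants. In Ccnd2 non-MCL primaries it was 986 ± 839 CPM (n = 3), with mice between 451 and 1950 CPM. The 2 transplant libraries labelled Ccnd2 non-MCL, from 1 mouse, had 45.8 and 83.4 CPM, below every primary with that genotype label. The p53-only tumours, which lack the transgene, still had 390 ± 386 CPM (n = 6), with mice between 5.49 and 893 CPM. Whether reads of the transgene are counted under Ccnd2 was not tested, so these levels do not establish the genotype labels. If they are counted there, the low level in those 2 transplant libraries goes against their label. Trp53 counts were low in every group, at 6 ± 4.29 CPM in MCL-like, 7.01 ± 4.87 CPM in Ccnd2 non-MCL and 11.7 ± 5.27 CPM in p53-only primaries. Reads from the 3' end of Trp53 can lie outside a floxed deletion, so they do not check it. Among the primary groups, Ccnd3, another G1 cyclin, had its lowest mean in MCL-like tumours. It was at 190 ± 42.8 CPM in MCL-like, 1130 ± 830 CPM in Ccnd2 non-MCL and 978 ± 1280 CPM in p53-only primaries. Cd5, a surface marker of B1a cells and of mantle cell lymphoma (chromosome 19, 10717116 to 10739002), was at 34.7 ± 9.83 CPM in MCL-like, 13.3 ± 22.4 CPM in Ccnd2 non-MCL and 6.59 ± 8.3 CPM in p53-only primaries. Ccnd2 non-MCL replicates 1, 2 and 3 had 0, 0.599 and 39.2 CPM of Cd5. Replicate 3 thus lay within the MCL-like range of 24.1 to 47 CPM. In MCL-like, Ccnd2 non-MCL and p53-only primaries, in that order, Ighd was at 55.9 ± 39, 52.8 ± 21.9 and 28.1 ± 18.1 CPM. Spn, which encodes a sialylated surface protein of B1 cells, was at 122 ± 52.2, 126 ± 45.9 and 66.4 ± 31.7 CPM. Fcer2a, a marker of follicular B cells, was at 5.75 ± 8.49, 0.895 ± 1.07 and 13.4 ± 24.6 CPM. Cd79a counts were low, at 10.2 ± 6.48, 12.2 ± 2.84 and 14.3 ± 9.84 CPM, while its partner chain Cd79b was at 237 to 1053 TMM-scaled CPM in primary mice. Whether the low Cd79a counts come from expression or from the counting was not settled. Sox11, a transcription factor expressed in many human mantle cell lymphomas, had a mean of 0 CPM in MCL-like primaries and transplants and at most 0.371 CPM in any mouse of the other groups.

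**Figure D1:**
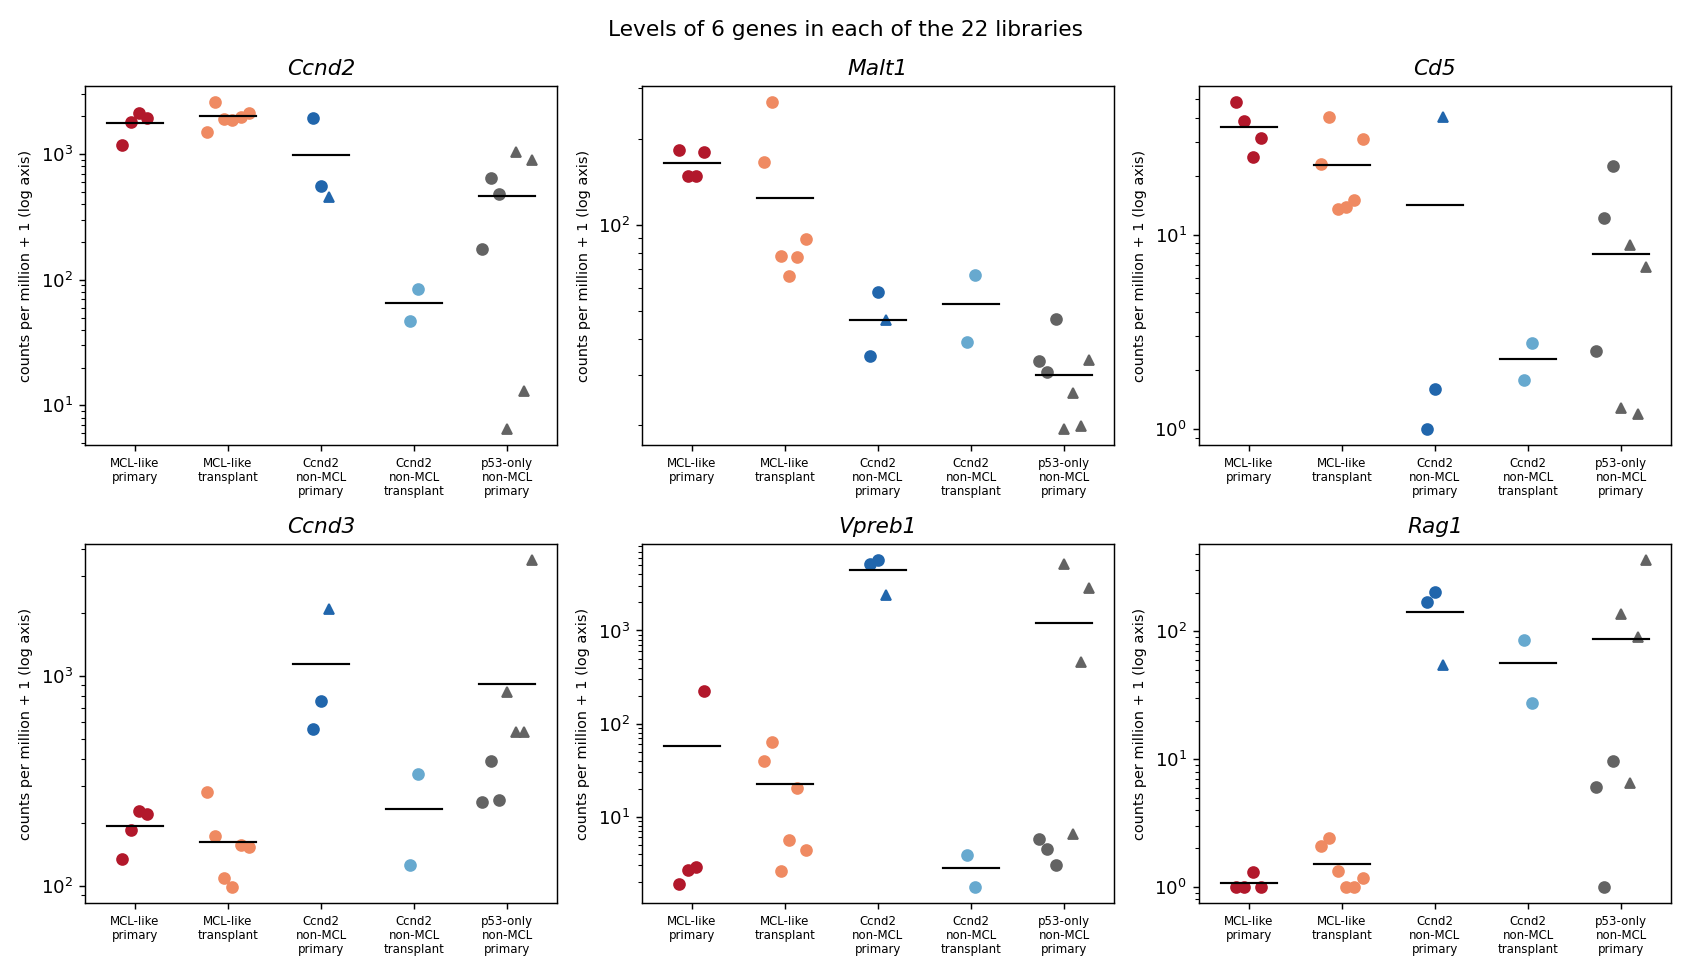
CPM plus 1, on a log axis, of Ccnd2, Malt1, Cd5, Ccnd3, Vpreb1 and Rag1 in each of the 22 libraries by group; circles are tumours with names starting TP, triangles those starting oTP, and bars are means over libraries. Malt1 lay between 147 and 182 CPM in MCL-like primaries and between 18.4 and 57.3 CPM in non-MCL primary mice. Among transplants the groups overlapped, with 65.2 to 267 CPM in MCL-like libraries and 38.1 and 65.8 CPM in those labelled Ccnd2 non-MCL.

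MCL-like and Ccnd2 non-MCL primary tumours share the genotype given in the labels, so comparing them asks what accompanies the MCL-like phenotype at the same genotype. The Ccnd2 non-MCL primaries all had high Vpreb1, a surrogate light chain of early B cells, at 2420 to 5690 CPM unscaled. MCL-like primaries had at most 224 CPM, so differences may follow that trait as well as the phenotype label. Malt1, a protease and scaffold that links antigen receptors to NF-kB (ENSMUSG00000032688, chromosome 18, 65430938 to 65479067), rose by 1.98 on the log2 scale (SE 0.37, adjusted p = 0.0484), from 44.0 ± 11.5 CPM (n = 3) to 173 ± 29.1 CPM (n = 4). Vpreb3, a partner of the pre-B cell receptor (chromosome 10, 75943057 to 75949657), fell by 4.24 (SE 0.75, adjusted p = 0.0471), from 1197 ± 243 to 63.4 ± 34.1 CPM. Of 12967 genes tested with edgeR, 8 rose and 32 fell. Ccnd2 itself was not called (log2 fold change 0.92, SE 1.2, adjusted p = 0.743).

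The largest increase was in Adm, which encodes the peptide hormone adrenomedullin (chromosome 7, 110627661 to 110629820), at 177 ± 104 against 7.01 ± 6.12 CPM (log2 fold change 4.60, SE 0.74, adjusted p = 0.0368). Eci1, an enzyme of fatty acid oxidation, rose by 2.63, and Plekhm3 by 2.57. Fcrla, an Fc receptor-like protein of B cells, rose from 27.0 ± 17.3 to 140 ± 32.4 CPM. It was not low in all non-MCL tumours: summed Fcrla counts were 7757 in p53-only and 1932 in MCL-like primary libraries, over more libraries in the p53-only group. Crbn, the substrate receptor of an E3 ubiquitin ligase, rose from 19.0 ± 6.74 to 70.7 ± 12.9 CPM, and Dram2, linked to autophagy, from 16.0 ± 1.84 to 57.6 ± 6.98 CPM. The mitochondrial transfer RNA mt-Tm rose by 2.36, although reads of neighbouring mitochondrial genes cannot be excluded from its counts. Among genes that fell, Cplx2, a regulator of vesicle fusion (chromosome 13, 54371349 to 54383917), went from 297 ± 27.7 to 15.5 ± 10 CPM. Rnase12 (log2 fold change -8.36) and Uaca (-7.45) fell, with wide spread among the Ccnd2 non-MCL mice at 565 ± 587 and 79.4 ± 98.4 CPM. Amotl1 fell by 5.70. Tiam1, an exchange factor for the GTPase Rac, fell from 38.9 ± 23.6 to 2.40 ± 1.55 CPM, and Thsd1 from 26.5 ± 10.8 to 1.62 ± 0.724 CPM. Pllp, a proteolipid (chromosome 8, 94674894 to 94696278), averaged 0.0608 CPM in MCL-like and 24.8 ± 17.5 CPM in Ccnd2 non-MCL tumours.

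The pro-B and pre-B list, which holds genes of the early B cell stages, fell as a list (camera adjusted p = 4.13e-14, median log2 fold change -4.97; adjusted p = 0.17 with an estimated correlation). Of its 16 tested members 1 was called over all genes and 15 were lower when adjusted over the list alone. Sox4, a transcription factor of early lymphocytes, was at 6.69 ± 6.89 against 265 ± 30.9 CPM (adjusted p = 0.0573), and Rag1, the recombinase of immunoglobulin genes (ENSMUSG00000061311, chromosome 2, 101638282 to 101649501), at 0.0844 against 140 ± 80.2 CPM (adjusted p = 0.0521). Vpreb1, a surrogate light chain, was at 51.9 ± 100.5 against 4356 ± 1857 CPM (adjusted p = 0.218). The MCL-like mean rested on replicate 4, with 224 CPM unscaled, against 0.892, 1.69 and 1.9 CPM in the other mice. The B1 cell list rose (median 2.59, camera adjusted p = 7.82e-09; adjusted p = 0.17 with an estimated correlation), with 0 of 16 members called by edgeR over all genes and 5 higher when adjusted over the list alone. Its member Arid3a, a transcription factor of B1 cells (chromosome 10, 79927043 to 79955018), was at 408 ± 100 against 83.4 ± 90.9 CPM (adjusted p = 0.0912). MHC class II genes, which present antigen, rose as a list, with all 10 members positive (median 3.73, camera adjusted p = 3.91e-09; adjusted p = 0.17 with an estimated correlation), with 0 called over all genes and 8 higher when adjusted over the list alone. H2-Aa was at 2647 ± 1303 against 82.5 ± 38.9 CPM (adjusted p = 0.0976), and H2-Eb1 had a log2 fold change of 4.74 (adjusted p = 0.105). H2-Aa was not low in all non-MCL tumours: it had 14906 counts in the transplants labelled Ccnd2 non-MCL, against 1486 in the primaries with that label. The corresponding H2-Eb1 counts were 9507 and 1326.

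NF-kB targets rose as a list, with 21 of 22 members positive (median 1.43, camera adjusted p = 4.47e-08; adjusted p = 0.17 with an estimated correlation), although 0 were called over all genes or when adjusted over the list alone. Nfkb1 had a log2 fold change of 1.45 (adjusted p = 0.103). B cell receptor signalling genes rose (median 0.96, camera adjusted p = 0.00107; adjusted p = 0.17 with an estimated correlation), with Malt1 called and 5 higher and 1 lower of 22 when adjusted over the list alone. Bcl10, which forms a complex with Malt1, was at 118 ± 12.1 against 48.4 ± 5.80 CPM (adjusted p = 0.0765). The early response to the receptor rose (median 1.30, camera adjusted p = 0.00573; adjusted p = 0.429 with an estimated correlation), with 0 of 13 called or passing when adjusted over the list alone. Marginal zone genes rose (median 1.55, camera adjusted p = 0.00501; adjusted p = 0.17 with an estimated correlation), with 2 of 8 higher when adjusted over the list alone, and Notch2 (log2 fold change 2.82, adjusted p = 0.0665) and S1pr3 (3.28, adjusted p = 0.0838) among them. Follicular genes (median 1.53, camera adjusted p = 0.0254; adjusted p = 0.394 with an estimated correlation) had 1 of 12 higher and 1 lower when adjusted over the list alone. General B cell genes rose (median 0.55, camera adjusted p = 0.0142; adjusted p = 0.336 with an estimated correlation), with 2 of 14 higher when adjusted over the list alone, and Cd37 at a log2 fold change of 1.57 (adjusted p = 0.0701). Proliferation genes fell as a list (median -0.43, camera adjusted p = 0.0173; adjusted p = 0.429 with an estimated correlation), with 0 of 22 passing when adjusted over the list alone and Birc5 at -1.39 (adjusted p = 0.126).

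Markers of other cells moved with these groups. T cell genes rose as a list (median 2.89, camera adjusted p = 0.00243; adjusted p = 0.429 with an estimated correlation), as did NK cell genes (median 1.37, camera adjusted p = 0.00968; adjusted p = 0.429 with an estimated correlation) and erythroid genes (median 1.66, camera adjusted p = 0.0391; adjusted p = 0.656 with an estimated correlation). When adjusted over the list alone, 1 T cell gene was lower, the kinase Zap70 (log2 fold change -2.84, adjusted p = 0.105 over all genes), and 0 NK cell or erythroid genes passed. Cd3e had 3.67 (adjusted p = 0.234). Summed over each list, T cell markers took 470 ± 151 CPM in MCL-like and 234 ± 104 CPM in Ccnd2 non-MCL tumours, and erythroid markers 60800 ± 36800 and 18200 ± 14700 CPM. Zap70 enters the T cell sum and had 1608 counts in Ccnd2 non-MCL primaries, where Cd3e had 30 and Cd3d 68. In MCL-like primaries the counts were 175, 306 and 593. Zap70 did not follow these T cell receptor genes, so the sums do not measure T cells alone. Lists that did not pass were germinal centre (adjusted p = 0.74), plasma cell (0.816), G1 cell cycle (0.816), p53 targets (0.546), Myc targets (0.544), interferon (0.09), macrophage (0.257), neutrophil (0.604), stroma and endothelium (0.634), thymic epithelium (0.0749, 1 tested member) and the key genes (0.0718). When adjusted over the list alone, 1 plasma cell gene, 1 G1 gene and 1 key gene were lower, 1 key gene and 1 thymic epithelium gene were higher, and 0 members of the other lists passed. With fry, 3 lists passed, namely pro-B and pre-B, B1 cell and B cell receptor signalling genes.

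The number of called genes depended on single mice. It was 7, 5, 0 (1766 at an unadjusted p under 0.05) and 3 without MCL-like replicates 1, 2, 3 and 4, 8 and 5 without Ccnd2 non-MCL replicates 1 and 2, and 23, 5 and 24 without p53-only replicates 4, 6 and 7, which enter through the shared spread, scaling and low-count filter. Without the tumours whose names start with oTP, 552 genes were called, 38 of them among the 40, and 19 with that name prefix as a covariate. With limma-voom over all libraries the split was 310 up and 281 down. With library size scaling it was 2 up and 31 down, and the median of all genes moved from -0.0446 to -0.16.

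Setting MCL-like tumours against all non-MCL primaries, with or without the transgene, asked which genes differ with the phenotype label. All 4 MCL-like mice carry the transgene and 6 of the 9 non-MCL mice do not, so differences may follow the genotype as well. They may also follow Vpreb1, at 458 to 5690 CPM unscaled in the Ccnd2 non-MCL primaries and p53-only replicates 4, 6 and 7. Sox5, a transcription factor (chromosome 6, 143828425 to 144781977), rose from 1.95 ± 1.93 CPM (n = 9) to 82.8 ± 29.8 CPM (n = 4), a log2 fold change of 5.36 (SE 0.75, adjusted p = 0.00561). Malt1 rose by 2.34 (SE 0.28, adjusted p = 0.00127) and Adm by 5.29 (SE 0.54, adjusted p = 0.000695). Rag1 was at 0.0844 CPM in MCL-like tumours, with 1 count in the group, and at 109 ± 111 CPM in non-MCL tumours (adjusted p = 0.0127). Of 12967 genes, 368 rose and 348 fell with edgeR, 716 in all. Neither Ccnd2 (log2 fold change 1.67, SE 0.89, adjusted p = 0.257) nor Cd5 (2.11, adjusted p = 0.219) was called.

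Other large increases were in Ackr2, a chemokine scavenging receptor (log2 fold change 5.26), Camk2n1, an inhibitor of the kinase CaMKII (5.03), Slc39a4, a zinc transporter (4.59), and the sialyltransferase St8sia6 (112 ± 104 against 4.62 ± 8.09 CPM). Fcrl5, an Fc receptor-like protein of innate-like B cells (chromosome 3, 87435773 to 87500678), rose by 4.99 (SE 0.83, adjusted p = 0.0081), and Neurod4 by 4.53. Reln, the extracellular protein reelin, fell by 6.52. Sox4 (log2 fold change -5.13), Cpm (-4.93), Olfml2b (-4.62) and Fam135a (-4.32) fell as well. Smtnl2 was at 0.0844 against 41.3 ± 55.5 CPM (adjusted p = 0.0391), and Pllp at 0.0608 against 13.8 ± 14.0 CPM (adjusted p = 0.0135). Vpreb1 was not called (adjusted p = 0.148), with a wide spread among non-MCL mice, at 2329 ± 2371 CPM.

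The B1 cell list rose, with all 16 members positive (median 2.7, camera adjusted p = 2.95e-13; adjusted p = 0.0778 with an estimated correlation), with 7 called and 11 higher when adjusted over the list alone. Arid3a rose by 2.83 (SE 0.44, adjusted p = 0.00561), Nfatc1, a transcription factor activated by calcium, by 2.55, and Fcrl5 is also a member. B cell receptor signalling genes rose (median 0.82, camera adjusted p = 8.76e-06; adjusted p = 0.0778 with an estimated correlation), with 5 of 22 called and 7 when adjusted over the list alone. They included Malt1, Bcl10 (log2 fold change 1.26, adjusted p = 0.0081) and the kinase Lyn (446 ± 80.1 against 187 ± 62.6 CPM, adjusted p = 0.0174). NF-kB targets rose as a list, with 21 of 22 members positive (median 0.97, camera adjusted p = 2.13e-07; adjusted p = 0.18 with an estimated correlation), with 5 called and 6 when adjusted over the list alone. They included the cytokine subunit Ebi3 (3.64, adjusted p = 0.0293), the adhesion molecule Icam1 (1.44, adjusted p = 0.0325) and the pathway's own members Nfkbid (1.96), Nfkbie (1.80) and Nfkb1 (1.13). The early receptor response did not pass (camera adjusted p = 0.063, 0 of 13 when adjusted over the list alone).

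Pro-B and pre-B genes fell as a list, with all 16 members negative (median -4.39, camera adjusted p = 2.58e-08; adjusted p = 0.18 with an estimated correlation), with 7 called and 13 when adjusted over the list alone, Vpreb3 among them at -3.81 (SE 0.69, adjusted p = 0.0108). General B cell genes rose (median 0.90, camera adjusted p = 0.000582; adjusted p = 0.18 with an estimated correlation), with 3 of 14 called and 3 when adjusted over the list alone: Cd37 by 1.94, the scaffold Bank1 by 2.68 and Ms4a1, a surface protein of mature B cells, by 3.18. Ms4a1 went from 167 ± 193 to 1518 ± 595 CPM. Marginal zone genes rose (median 1.01, camera adjusted p = 0.00458; adjusted p = 0.18 with an estimated correlation), with S1pr3 called at 4.20 (adjusted p = 0.00561) and 2 of 8 when adjusted over the list alone. Follicular genes rose as a list (median 0.86, camera adjusted p = 0.012; adjusted p = 0.283 with an estimated correlation), with S1pr1, a receptor that guides lymphocyte egress, called up (2.56, adjusted p = 0.00754), Bach2, a transcriptional repressor, called down (-3.42, adjusted p = 0.0213), and 2 up and 1 down when adjusted over the list alone. MHC class II genes were positive in all 10 members (median 2.04, camera adjusted p = 9.79e-06; adjusted p = 0.257 with an estimated correlation), with 0 called by edgeR over all genes and 1 when adjusted over the list alone. H2-Oa had 2.22 (adjusted p = 0.0522) and Cd74 2.53 (adjusted p = 0.0905). Interferon genes rose (median 0.70, camera adjusted p = 0.00207; adjusted p = 0.399 with an estimated correlation), with 1 of 15 called, the RNA sensor Ddx58 (1.95, adjusted p = 0.0149), and 1 when adjusted over the list alone. The key genes rose (median 0.64, camera adjusted p = 0.012; adjusted p = 0.18 with an estimated correlation), with Malt1 called and 2 up and 1 down of 12 when adjusted over the list alone. Ccnd3 was at -2.29 (adjusted p = 0.0576) and Ighm at 1.44 (adjusted p = 0.0818).

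Proliferation genes fell as a list, with 21 of 22 members negative (median -0.77, camera adjusted p = 2.01e-05; adjusted p = 0.2 with an estimated correlation). Birc5, an inhibitor of apoptosis that acts in mitosis (-1.52, adjusted p = 0.0285), and Cdc20, an activator of mitotic exit (-0.95, adjusted p = 0.0458), were called, and 3 were lower when adjusted over the list alone. Myc targets fell (median -0.60, camera adjusted p = 0.00905; adjusted p = 0.498 with an estimated correlation), with Cad, an enzyme of pyrimidine synthesis, called (-1.06, adjusted p = 0.0384) and 2 of 18 when adjusted over the list alone. T cell genes (13 of 14 members positive, camera adjusted p = 0.00451; adjusted p = 0.432 with an estimated correlation), NK cell genes (median 1.66, camera adjusted p = 0.0084; adjusted p = 0.399 with an estimated correlation) and erythroid genes (median 2.06, camera adjusted p = 0.000299; adjusted p = 0.356 with an estimated correlation) rose as lists, with 0 members passing over all genes or when adjusted over the list alone. Cd28 had 3.24 (adjusted p = 0.0875) and Hbb-bs 2.91 (adjusted p = 0.0828). Lists that did not pass were germinal centre (adjusted p = 0.201), plasma cell (0.957), G1 cell cycle (0.869), p53 targets (0.601), macrophage (0.199), neutrophil (0.957), stroma and endothelium (0.905) and thymic epithelium (0.261, 1 tested member). When adjusted over the list alone, 1 plasma cell gene was higher and 2 were lower, and 0 members of the other lists passed. For the plasma cell list the median was 0.27, the mean -0.03 and the test's direction up, and for p53 targets the median was -0.11, the mean -0.06 and the test's direction up. With fry, 10 lists passed.

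**Figure D2:**
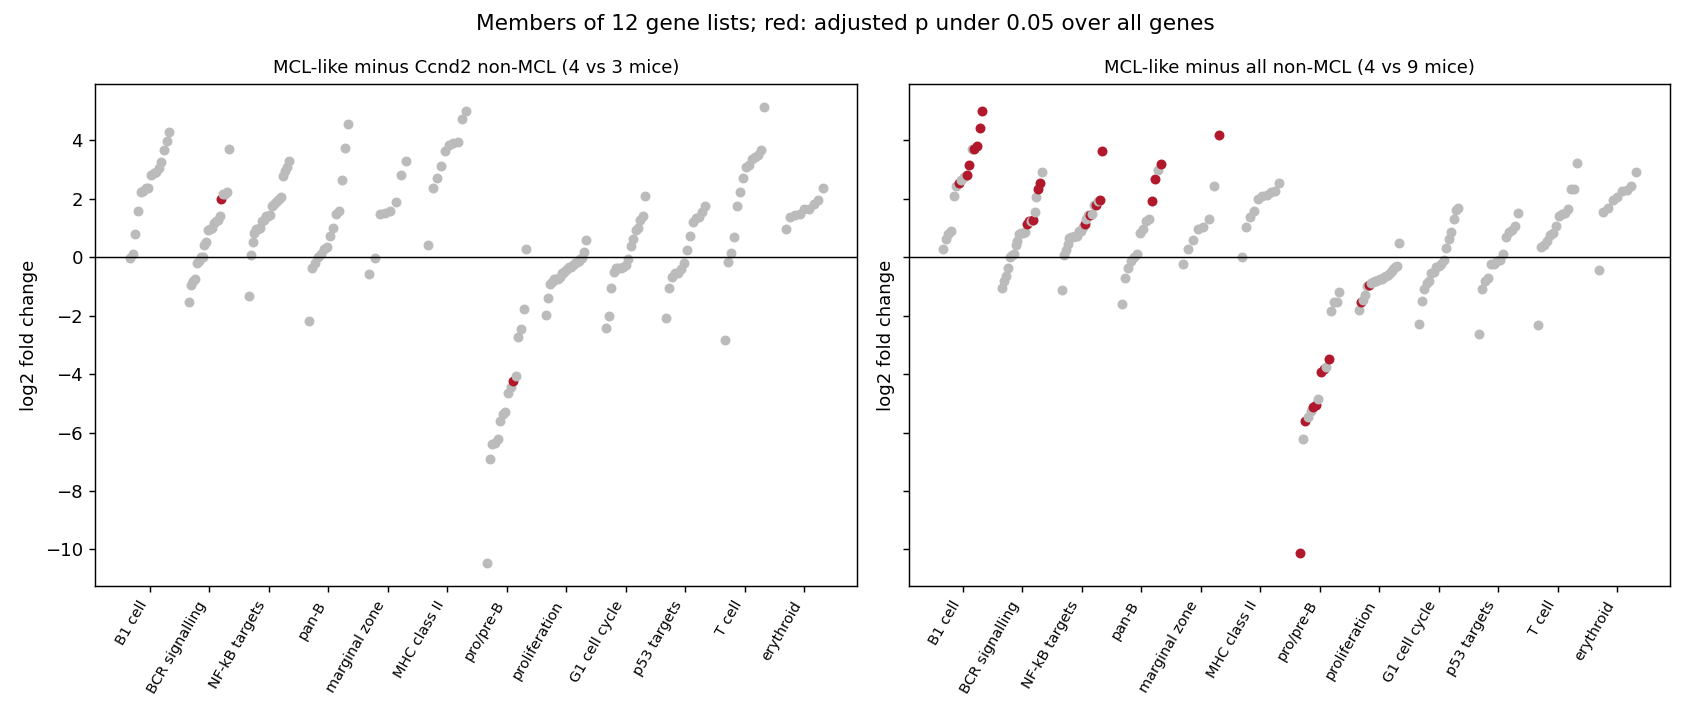
Log2 fold change of each tested member of 12 gene lists, in MCL-like against Ccnd2 non-MCL primaries and in MCL-like against all non-MCL primaries; red points had an adjusted p under 0.05 over all genes and grey points did not. Pro-B and pre-B genes lay below 0 in 15 of 16 and 16 of 16 members, and B1 cell genes above 0 in 15 of 16 and 16 of 16.

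Tumours with names starting oTP stood apart. The mitochondrial ribosomal RNA mt-Rnr1 was at 582 to 865 CPM in the 5 oTP libraries and 3130 to 11600 CPM in the 17 TP libraries, mt-Rnr2 at 2380 to 5710 and 12700 to 31200 CPM, and no MCL-like library was an oTP sample. Without oTP libraries, 248 genes were called between MCL-like and all non-MCL tumours, 190 of them among the 716, and with the prefix as a covariate 213, of which 177 were among the 716. Spleen tumours alone gave 37. The count was 188, 250, 176 and 191 without MCL-like replicates 1, 2, 3 and 4, 1091 without Ccnd2 non-MCL replicate 2, and 440, 395 and 418 without p53-only replicates 4, 6 and 7. The balance of higher and lower genes moved with the setting: 309 rose and 439 fell with library size scaling and 798 and 1015 with DESeq2, against 325 and 194 without a count filter, 176 and 72 without oTP libraries, 131 and 45 without MCL-like replicate 3, and 1083 and 733 with limma-voom.

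The effect of the transgene among non-MCL tumours was asked by comparing Ccnd2 non-MCL with p53-only primaries. Ccnd2 was at 972 ± 854 CPM (n = 3) against 383 ± 369 CPM (n = 6), a log2 fold change of 1.34 (SE 1.05, adjusted p = 0.666). With edgeR 0 of 12967 genes were called, 1330 had an unadjusted p under 0.05, and DESeq2 called 129. Prkcb, a protein kinase of the B cell receptor pathway, had a log2 fold change of 1.52 (SE 0.40, adjusted p = 0.311), at 831 ± 262 against 290 ± 94.7 CPM, and Ccnd1, another D-type cyclin, -3.70 (SE 1.36, adjusted p = 0.417). Malt1 had 0.58 (adjusted p = 0.539).

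As lists, pro-B and pre-B genes (median 0.91, camera adjusted p = 0.00176), interferon genes (0.43, adjusted p = 0.0343) and erythroid genes (0.65, adjusted p = 0.0286) were higher in Ccnd2 non-MCL tumours. MHC class II genes (median -1.99, camera adjusted p = 0.00176), proliferation genes (-0.47, adjusted p = 0.00176), Myc targets (-0.57, adjusted p = 0.00176) and the early receptor response (-0.73, adjusted p = 0.0343) were lower. Each of these 7 lists had an adjusted p = 0.801 with an estimated correlation. With fry 0 of 24 lists passed in this comparison. Adjusted over the list alone, 3 MHC class II genes were lower and 0 members of the other 6 lists passed. H2-Aa was at 82.5 ± 38.9 against 863 ± 1067 CPM, and its activator Ciita had a log2 fold change of -3.37 (adjusted p = 0.408). The transcription factor Myc was at 21.1 ± 19.1 against 104 ± 98.0 CPM (adjusted p = 0.38), and the ribosome assembly gene Npm1 at -1.23 (adjusted p = 0.445). The replication gene Mcm6 was at 175 ± 35.2 against 336 ± 52.9 CPM (adjusted p = 0.332) and Ccna2, a cyclin of S phase, at -1.04 (adjusted p = 0.417). Vpreb2, a surrogate light chain, had 3.72 (adjusted p = 0.46) and the receptor Kit of early progenitors 2.66 (adjusted p = 0.389). The count was 8 without Ccnd2 non-MCL replicate 3 and 7 without p53-only replicate 7. It was 116 without oTP libraries and 1 with the prefix as a covariate.

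MCL-like tumours were compared before and after transplantation in the 3 mice with both, which asked what changes in an immunodeficient host. Ccnd2 was at 2075 ± 125 CPM in transplants and 1569 ± 249 CPM in primaries (n = 3 pairs), a log2 fold change of 0.41 (SE 0.40, adjusted p = 0.855). Malt1 had -0.52 (adjusted p = 0.82), Cd5 -0.64 (adjusted p = 0.82) and Ighm 0.63 (adjusted p = 0.849). With edgeR 0 of 12020 genes were called, 656 had an unadjusted p under 0.05, and DESeq2 called 29. The lists of T cell, NK cell and erythroid markers fell in transplants with the preset correlation, each with an adjusted p = 0.474 with an estimated correlation, although summed erythroid markers were higher after transplantation in 1 of the 3 mice.

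T cell genes had all 14 members negative (median -2.56, camera adjusted p = 1.71e-17; adjusted p = 0.474 with an estimated correlation), 6 of them lower when adjusted over the list alone. Cd3d, a chain of the T cell receptor complex, was at 4.65 ± 2.22 CPM in transplants and 30.8 ± 18.1 CPM in primaries (adjusted p = 0.749), and Cd4 had -3.35 (adjusted p = 0.749). NK cell genes (median -2.88, camera adjusted p = 7.74e-08; adjusted p = 0.474 with an estimated correlation) had 3 of 5 lower when adjusted over the list alone, with the protease Gzma at 1.37 ± 2.07 against 9.02 ± 2.10 CPM (adjusted p = 0.82). Erythroid genes (median -3.44, camera adjusted p = 5.05e-06; adjusted p = 0.474 with an estimated correlation) had 1 lower when adjusted over the list alone, and Hba-a2, whose reads can be shared with its copy Hba-a1, had -9.40 (adjusted p = 0.749). Over all libraries of a group, Hba-a2 had 168644 counts in MCL-like primaries and 421 in MCL-like transplants, and Hbb-bs 389978 and 195505. In the transplants labelled Ccnd2 non-MCL, Hba-a2 had 26 counts and Hbb-bs 6109. Hba-a2 did not follow Hbb-bs, so its fall does not measure erythroid cells alone. In 1 of the 3 mice the summed erythroid markers were higher after transplantation, at 71700 CPM against 50400 CPM in primary replicate 1, with 119000 CPM in transplant replicate 1 and 10900 CPM in transplant replicate 2. Macrophage genes (median -0.49, camera adjusted p = 0.0072), stroma and endothelium (-0.85, adjusted p = 0.00207) and marginal zone genes (-0.62, adjusted p = 0.00761) each had 1 member lower when adjusted over the list alone, and follicular genes (-0.55, adjusted p = 4.17e-05) had 2. All 4 lists had an adjusted p = 0.474 with an estimated correlation. Lyz2, lysozyme of myeloid cells, was at 84.5 ± 52.2 against 333 ± 50.1 CPM (adjusted p = 0.82), and Cr2, the complement receptor CD21, had -3.09 (adjusted p = 0.749).

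MHC class II (median -0.60, camera adjusted p = 0.000122), interferon (-0.71, adjusted p = 0.000122), general B cell (-0.53, adjusted p = 0.00207) and key genes (-0.44, adjusted p = 0.0338) also fell as lists, with an adjusted p = 0.474 with an estimated correlation and 0 members passing when adjusted over the list alone. Oasl2, an interferon response gene, had -2.30 and H2-DMa -0.76 (adjusted p = 0.82 for both). Plasma cell genes rose as a list, with all 9 members positive (median 0.81, camera adjusted p = 4.78e-08; adjusted p = 0.474 with an estimated correlation), with 2 when adjusted over the list alone. Jchain, which joins IgM into polymers, had 1.82 (SE 0.39, adjusted p = 0.749), and Derl3, of the endoplasmic reticulum, 1.52 (adjusted p = 0.82). Proliferation genes (median 0.43, camera adjusted p = 0.000373; adjusted p = 0.474 with an estimated correlation) and Myc targets (0.42, camera adjusted p = 0.000321; adjusted p = 0.527 with an estimated correlation) rose, with 0 members passing when adjusted over the list alone. Birc5 had 0.62, Ncl 1.04 and the cell cycle inhibitor Cdkn1a 1.45 (adjusted p = 0.82 for each). With fry 0 of 24 lists passed. The count was 14 genes without replicate 1 and 9 without replicate 2, and with library size scaling the median of all genes moved from 0.01 to -0.10.

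The 40 genes called between MCL-like and Ccnd2 non-MCL primaries were followed in mice outside that comparison, MCL-like transplant replicate 5 against the transplants labelled Ccnd2 non-MCL, whose Ccnd2 level was low (64.9 CPM). Of 39 genes with counts, 35 (89.7%, exact Clopper-Pearson 95% interval 75.8 to 97.1) had the same direction, against 63.3% of 12865 other genes. The 4 exceptions were Cplx2 (log2 difference 1.71), Tiam1 (0.29), Rnase12 (0.28) and Fcrla (-0.60), all called in primaries with the opposite sign. A shared direction does not show a shared size. Adm differed by 7.37 and Vpreb3 by -2.42, but Malt1 by 0.54 against 1.98 in primaries and Plekhm3 by 0.31 against 2.57. Some genes were near the floor, with Pllp at 0 against 0.259 CPM and Rnase12 at 0.687 against 0.389 CPM. Genes are not independent replicates, and replicate 5 resembled tumours of a mouse used in the comparison.

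Heavy chain transcripts were compared by class. Ighm took 98 ± 0.456% of heavy chain constant region counts in 5 MCL-like mice (97.4 to 98.6%) and 68 ± 34.9% in 10 non-MCL mice (0.458 to 99.4%), a test chosen after the values were seen (two-sided exact permutation p = 0.0506). Without oTP libraries the p was 0.026 by the same exact permutation test (5 vs 6 mice). With transplant replicate 5 counted under the mouse of replicates 3 and 4 it was 0.0769 by that test (4 vs 10 mice). Ighg1 took 93.8% (95% interval 93.4 to 94.2) and 90.1% (89.6 to 90.6) in the transplants labelled Ccnd2 non-MCL, and Ighg2b 74.5% (73.9 to 75.1) in p53-only replicate 3. Few reads fell in V segments: by the minimum of 50 counts, 0 MCL-like mice and 1 non-MCL mouse could be used, so no test was possible. Ighv11-2, a segment used by B1a cells, took 38 of 38 counts in MCL-like primary replicate 2. With a minimum of 20 counts, 1 of 1 MCL-like and 0 of 2 non-MCL mice had it as the leading segment, which gives a two-sided Fisher exact p of 0.333.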

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

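The test of the V segment of MCL-like transplant replicate 5 and the comparison of its distances were chosen after the result was seen; the tests of tumour name prefix, host cells and other splits were not. Single libraries standing far from the rest of their group were sought in 54 sets of libraries, and 13 stood out by the gap to the nearest library relative to the range. Chance gives about 1 in 20 only if libraries are independent and values normally distributed. The values were CPM without a log scale, and all 13 were the highest of their set, so their number cannot be set against that rate. The libraries were also not all independent: MCL-like transplant replicates 1 and 2, replicates 3 and 4, and p53-only replicates 2 and 5 share a mouse.

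The p53-only group held 6 of these. Ccnd1 was at 425 CPM in replicate 1, with the next library at 158 CPM. Ccnd3 reached 3550 CPM in replicate 7, against 837 CPM in the next. Cd79a, whose low counts were not settled as expression or counting, was at 55.9 CPM in replicate 5, against 26.9 CPM. NK cell markers summed to 462 CPM in replicate 3, against 102 CPM, and neutrophil markers to 4560 CPM there, against 825 CPM. Erythroid markers summed to 39000 CPM in replicate 1, against 16900 CPM. Among MCL-like primaries, Ccnd1 was at 74 CPM in replicate 1 (next 24.7 CPM), Cd79a at 19.9 CPM in replicate 4 (next 6.96 CPM) and Fcer2a at 18.4 CPM in replicate 3 (next 2.96 CPM). Among MCL-like transplants, Ccnd1 was at 100 CPM in replicate 2, a tumour of the mouse whose primary had 74 CPM. The next library, at 20.9 CPM, was replicate 1 of that same mouse. Spn was at 237 CPM in transplant replicate 6 (next 89.2 CPM). Ighm was at 35800 CPM in transplant replicate 1 (next 16000 CPM), and erythroid markers at 119000 CPM in the same library (next 10900 CPM).

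A first pattern concerned the tumour name prefix, since 5 of the 9 non-MCL mice and no MCL-like mouse had an oTP library. Without those libraries 711 of 711 called genes kept their direction. The median ratio of the new to the old log2 fold change was 0.9 (quartiles 0.803 to 1.01). Both fits share the MCL-like mice and the TP libraries, and the genes were chosen on these values, so this agreement was partly built in. For the 190 of the 716 genes that were also called without oTP libraries, the values argue against the prefix as the whole cause. For the rest of the 716 differences between MCL-like and all non-MCL tumours, the prefix stays open. None of the other splits drawn at random gave as many genes (1 of 100 splits, the real one included, highest other 65). The split of the 4 mice with oTP libraries alone from the other 9 gave 1754 genes, more than the real 716, which points to a structure of the samples that follows the prefix; 248 genes were called without oTP libraries and 213 with the prefix as a covariate. What the prefix stands for, and differences of tumour site or stage that may go with it, stay open.

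A second pattern was that T cell, NK cell and erythroid markers were higher as lists in MCL-like primaries with the preset correlation, so normal spleen cells might carry the genes called higher there. With an estimated correlation these lists did not pass (adjusted p = 0.432, 0.399 and 0.356 against all non-MCL), and 0 of their members passed as higher. Those genes would then fall in immunodeficient hosts as T cell markers do. The 366 tested genes had a median log2 fold change of -0.304 from primary to transplant (quartiles -0.603 to 0.0612), against -2.56 for T cell markers (quartiles -2.99 to -1.50), and 1 of 366 lay at or below the T cell median. This argues against normal T cells as the source for the genes as a set; host cells that also populate NSG spleens, and single genes, stay open.

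Another pattern was the likeness of MCL-like transplant replicate 5, which the labels give to a mouse of its own, to replicates 3 and 4 from another mouse. Its distances to them, as the SD of log2 CPM differences over 8939 genes, were 0.391 and 0.42, near the 0.358 between replicates 3 and 4, while replicate 6 from a further mouse was 2.17 times as far on average (0.861 and 0.897), which argues against all transplants being alike for want of host tissue. Ighv1-69 took 100% of its V segment counts (12 of 12, exact 95% interval 73.5 to 100), 26 of 26 in the libraries of the other mouse, and 0 of 461 in the 18 libraries of other mice. A shared tumour origin, or a mixed-up label, is a candidate explanation that the counts leave open; an independent tumour using the same segment was not tested.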

How the results depend on the processing

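Leaving out haemoglobin, mitochondrial and Gm42418 counts, placing transplant replicate 5 under another mouse, counting V segments over all libraries, and following the genes called against all non-MCL mice were chosen after seeing the data. No named gene or list changed direction where it had passed its test, under any alternative run. Lists were rerun only with an estimated correlation, fry and RLE scaling, and the estimated correlation keeps the direction of the main run. Most settings for genes reuse largely the same libraries, so kept directions are weak evidence. Over named genes and settings, the side of the threshold was kept, a call lost and a call gained in 679, 191 and 64 results against Ccnd2 non-MCL and in 1082, 159 and 22 against all non-MCL; for the transgene 4 of these results and for transplants 15 passed a threshold they had missed. Against Ccnd2 non-MCL, the 40 genes became 22 with RLE scaling (4 up, 18 down), 895 with DESeq2, 19 with a filter of 1 CPM, 371 with the 2 groups alone, 474 with all mice, 62 with replicate 5 under another mouse, 591 with limma-voom over all libraries, 116 in spleen tumours, 552 without oTP tumours (38 of the 40 shared) and 19 with the prefix as a covariate; leaving out a mouse gave 0 to 54 (0 without MCL-like replicate 3, where 1766 had an unadjusted p under 0.05). Against all non-MCL, the 716 became 1813 with DESeq2, 1476 with all mice (544 with replicate 5 under another mouse), 1816 with limma-voom, 37 in spleen tumours, 248 without oTP tumours and 213 with the prefix as a covariate, and leaving out a mouse gave 176 (without MCL-like replicate 3) to 1091 (without Ccnd2 non-MCL replicate 2). For the transgene, the 0 genes with edgeR became 129 with DESeq2, 2 without a count filter, 41 in spleen tumours, 116 without oTP tumours and 1 with the prefix as a covariate, and leaving out a mouse gave 0 to 8. For transplants, the 0 genes became 29 with DESeq2, 35 without a count filter and 3 with limma-voom, leaving out a mouse gave 0 to 14, and without the pairing (no replicate block) there were 0 (253 at an unadjusted p under 0.05). The 13, 15, 7 and 14 lists past the threshold became 0 each with an estimated correlation, and 3, 10, 0 and 0 with fry. A leading Ighv11-2 went from 0 to 1 mouse with at least 20 V segment counts, and to 1 with all libraries and at least 10. The estimated correlation allows for genes of a list moving together; for the other settings the cause was not tested. Without haemoglobin, mitochondrial and Gm42418 counts 30 and 698 genes were called, and 91.9% of the genes followed in other mice kept their direction with at least 10 counts, 84.5% for the genes called against all non-MCL.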

Other observations

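The test of the IgM share was chosen after the result was seen, as was the count of V segments over all libraries of a mouse; the counts of other splits were planned.

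Surrogate light chain and recombinase transcripts split the p53-only tumours. Vpreb1 was at 5130, 2880 and 458 CPM in replicates 4, 7 and 6 and between 2.02 and 5.45 CPM in replicates 1, 2, 3 and 5, while the Ccnd2 non-MCL primaries had 5230, 5690 and 2420 CPM. In the transplant mouse labelled Ccnd2 non-MCL Vpreb1 was at 1.81 CPM and Igll1, the other surrogate light chain, at 0.648 CPM, yet Rag1 was at 55.2 CPM and Ighg1 led the heavy chain counts. V segment counts pointed to a leading segment in mice of both phenotypes. Over all libraries of a mouse, Ighv1-53 took 147 of 148 counts in that of MCL-like primary replicate 1 and Ighv11-2 took 100 of 101 in that of MCL-like primary replicate 2. Ighv4-1 took 68 of 80 counts in p53-only replicate 7 and Ighv9-3 took 29 of 39 in Ccnd2 non-MCL primary replicate 2. With at least 10 counts, Ighv11-2 led in 1 of 4 MCL-like and 0 of 8 non-MCL mice (two-sided Fisher exact p = 0.333).

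Class-switched transcripts may be rarer in MCL-like than in non-MCL tumours, which was put to a two-sided exact permutation test of the share of Ighm (p = 0.0506 over 3003 splits of 15 mice). With transplant replicate 5 counted under the mouse of replicates 3 and 4 the exact permutation p was 0.0769, and without oTP libraries it was 0.026. The permutation p lay on both sides of 0.05 over these settings, and the test was chosen after the values were seen, so it does not decide.

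The number of called genes was set against other splits of the same mice. For MCL-like against Ccnd2 non-MCL, 1 of 35 splits gave as many as 40 genes, the real one itself, and the highest other gave 0. A share of 1 in 35 is the lowest that these splits can give, and without MCL-like replicate 3 the real count was itself 0. A chance split is thus made less likely for the full set of mice, but is not excluded. For Ccnd2 non-MCL against p53-only, the real count was 0, which all 84 of 84 splits reach by definition, so the count says nothing about chance. The highest other split gave 311 and set the mice of p53-only replicates 1, 2 and 3 against the rest, which points to a structure within the non-MCL samples that the genotype does not follow. These are the p53-only mice with a TP library, 1 of which also gave the oTP library of replicate 5, and the primary non-MCL mice with low Vpreb1. The other p53-only mice, replicates 4, 6 and 7, with oTP libraries alone and higher Vpreb1, gave 170 against the rest. For transplant against primary, the 4 splits that part each pair are too few for a share under 0.05; the real count was 0, which 4 of 4 reach by definition, with 69 in the highest other.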
